A study of Arabidopsis thaliana with 27 samples.

How the data were processed

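RNA from rosette leaves and inflorescences of Arabidopsis thaliana was measured on Affymetrix ATH1 arrays, which hold 22810 probe sets. Each of the 27 arrays was placed in 1 of 9 groups of 3 from its label: Col-0, dcl4-2, rdr6-15 and dcl1-7 in leaf (12 arrays), and Col-0 set A, dcl4-2, rdr6-15, Col-0 set B and dcl1-7 in inflorescence (15 arrays). Per the labels, set A is the control of dcl4-2 and rdr6-15 and set B is the control of dcl1-7, so each mutant was set against the Col-0 arrays named for it. The series' design text describes the 3 arrays of a group as biological replicates of at least 9 plants each.

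The deposited values are log2 expression summaries, 1 per probe set and array, made by the authors with RMA (background correction, normalization between arrays and summary over probes), per the submitters' processing notes. The RMA version, and whether leaf and inflorescence arrays were normalized together, are not given in the sources used here. The log2 scale was read from the deposited values, whose array medians lay between 6.93 and 7.00 in leaf and between 7.04 and 7.17 in inflorescence. RMA compresses differences of weakly expressed genes and equalizes the arrays, so a shift of all transcripts at once would not be seen. Arrays carry no read depth, and the number of arrays limits the precision.

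The 64 Affymetrix control probe sets were left out of the tests, which leaves 22746, and no filter on low signal was applied in the reported values. Probe sets were named from GEO's platform annotation, which gives 1 symbol for 13513 of the tested probe sets, several for 503 and none for 8730. No gene was named from a probe set with several symbols. The named probe sets cover 13355 genes, and 13436 probe sets matched a locus in a RefSeq gene table of assembly TAIR10.1, used for names and for which genes neighbour each other. No coordinates are printed, since the values name no genome build. A gene with several probe sets (147 genes) is represented by the one with the highest mean, and in 0 of these genes were probe sets called in opposite directions in any mutant comparison. No probe set carries DCL4, RDR6 or DCL1 as its single symbol in the annotation used here, so the mutated genes could not be used to check the labels. The same holds for the trans-acting siRNA precursors and for the ARF and HTT genes among the siRNA targets, which are not analysed here. The list of pentatricopeptide repeat genes of the RFL clade, which is analysed, holds several other targets of such siRNAs or of microRNAs.

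Group means were fitted to the log2 values with limma 3.58.1 in R 4.3.3 (lmFit, eBayes), separately for the 12 leaf and the 15 inflorescence arrays, so that the groups of a tissue share an estimate of the spread. Probe sets with a Benjamini-Hochberg adjusted p under 0.05 over the 22746 are called. Changes are differences of log2 means, mutant minus Col-0, with the standard error (SE) of the fit. Group values are means ± SD over n = 3 arrays. Whether an effect differs between tissues was tested as an interaction in a fit of all 27 arrays. The comparisons, the tests, most alternatives and the rule for named genes were chosen before the data were examined.

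The rule named, per mutant comparison, the 6 genes with the largest rise and the 6 with the largest fall among called probe sets in which all 3 mutant values lay outside the range of the 3 Col-0 values (10% of unchanged probe sets do so by chance). It also named up to 4 members with the smallest p of each gene list described, whose arrays may overlap. Most genes named outside this rule are said to be so. Tissue differences were also given for genes named in a comparison of the same mutant with Col-0. Fixed gene lists were counted with the adjusted p over all probe sets and again adjusted over the list alone. Lists with at least 3 measured members were tested with camera (limma, two-sided) at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over 180 tests. Members counted as measured are those with a probe set of a single symbol, and the other listed genes were not tested. The 10 measured microRNA targets, for example, are only a part of that list, so their counts do not stand for such targets in general. Because many listed genes had no probe set with a single symbol, further lists were written after the annotation but before any fold change was seen. These are the lists for autophagy, SWEET transporters, tau glutathione transferases, nuclear photosynthesis genes, plastid and mitochondrial transcripts, stomata, meiosis, flower and meristem regulators, cell wall loosening, trichomes, roots, cytokinin response regulators and wider lists for pollen, tapetum, cold, jasmonate, defence, heat, flavonoids, seed storage and auxin. With the estimated correlation no list passed in any comparison, so every list shift below rests on the preset correlation.

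Overlap of dcl4-2 and rdr6-15 effects was set beside 100 simulated draws of unchanged groups with a shared simulated control, and beside the overlap of independent lists. Calls within up to 500 measured genes on each side of the mutated gene were compared with all other genes by Fisher's exact test. RNA integrity was read from the Affymetrix control probe sets at the 3' and 5' ends of the GAPDH, actin and ubiquitin transcripts, as the mean 3' minus 5' log2 difference.

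The pipeline was tested on simulated data with 50 changed probe sets per fold size among 22746. For the dcl4-2 leaf comparison, 26% of probe sets changed by 0.5 on the log2 scale were recovered, 72% at 1, 100% at 2 and 88% at −1, with 9 false among 152 calls. For the dcl1-7 inflorescence comparison, the shares were 58%, 94%, 96% and 88%, with 3 false among 171 calls.

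Alternatives were quantile normalization or median centring of the deposited values, fits of only the groups compared or of all 27 arrays, array weights, a trended and robust variance model, leaving out the most weakly expressed probe sets (25% or 50% of them, by mean; 25% for the gene lists) or probe sets without a single gene, an adjusted p of 0.01, a 2-fold minimum, the other or both Col-0 inflorescence sets as control, other window sizes around the mutated genes, and leaving out each replicate in turn. Fits without 3 arrays that deviate together, gene lists and interactions of dcl1-7 against set A, and calls in the same direction against both sets were added after seeing the data. Replicate numbers follow only the order of deposit, so no array was paired with another.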

Results

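Transcript levels were measured in Arabidopsis plants of the wild type Col-0 and of 3 mutants of the small RNA machinery. DICER-LIKE 4 (DCL4) is the RNase III enzyme that cuts trans-acting siRNAs from double-stranded RNA, RNA-DEPENDENT RNA POLYMERASE 6 (RDR6) makes that double strand, and DICER-LIKE 1 (DCL1) cuts microRNAs from hairpin precursors. The mutants are dcl4-2, rdr6-15 and dcl1-7. Rosette leaves 5 to 8 of each genotype (12 arrays) and inflorescences with flowers of stages 1 to 12 (15 arrays) were hybridised to 27 ATH1 arrays, with n = 3 biological replicates per group. Col-0 inflorescences were sampled in a pair of sets, A as the control of dcl4-2 and rdr6-15 and B as the control of dcl1-7. Values are log2 RMA summaries, and arrays of a group correlated at 0.980 to 0.998 across probe sets. For dcl1-7 leaf replicate 1 the correlations within its group were 0.982 and 0.9799. This array correlated more highly with Col-0 leaf replicate 2 (0.983), Col-0 leaf replicate 3 (0.9826) and rdr6-15 leaf replicate 1 (0.9846).

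**Figure D1:**
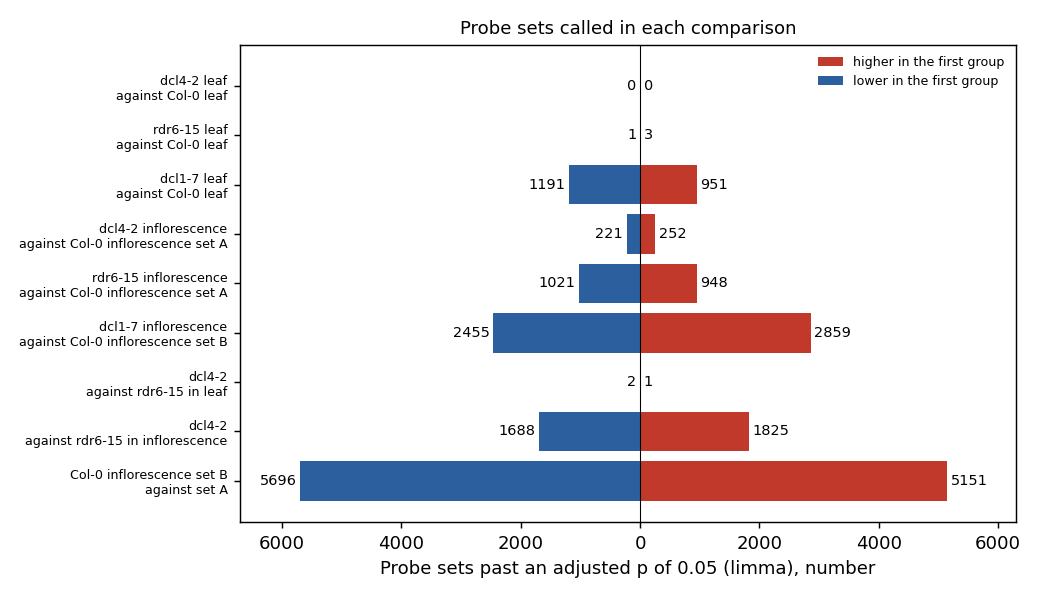
Number of probe sets past an adjusted p of 0.05 (limma) in each comparison; red bars to the right count those higher in the first group named and blue bars to the left those lower. The bars range from 0 in either direction for dcl4-2 leaf to 5151 and 5696 for the comparison of the Col-0 inflorescence sets.

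In leaf, the comparison of dcl4-2 with Col-0 asks what changes when trans-acting siRNAs are not cut by DCL4. AT1G12775, a pentatricopeptide repeat gene of the RFL clade that includes small RNA targets, was at 6.20 ± 0.09 in dcl4-2 and 5.20 ± 0.10 in Col-0, a difference of 1.00 (SE 0.18) that missed the threshold over all probe sets (adjusted p = 0.35). It was 1 of 15 RFL genes past the threshold adjusted over the list alone (list adjusted p = 0.166). QQS, a gene known only from Arabidopsis that affects starch content, was at 8.57 ± 0.33 against 8.03 ± 0.24, a difference of 0.53 (SE 0.18, adjusted p = 1). It was named after its values were seen. As groups, the 3 auxin-responsive genes lay higher. The median was 0.52 (camera adjusted p = 0.0113, and adjusted p = 0.324 with an estimated correlation). All 10 autophagy genes lay higher. The median was 0.18 (adjusted p = 0.00917, and adjusted p = 0.69 with an estimated correlation). Of the 21 defence genes of the wider list 17 lay lower. The median was −0.20 (adjusted p = 0.00246, and adjusted p = 0.461 with an estimated correlation). So did 49 of 66 plastid transcripts. The median was −0.12 (adjusted p = 0.00574, and adjusted p = 0.789 with an estimated correlation). The 4 anther and tapetum genes, markers of another organ, all lay lower. The median was −0.17 (adjusted p = 0.0362, and adjusted p = 0.324 with an estimated correlation). Without the most weakly expressed probe sets this list did not pass (adjusted p = 0.145). By limma, 0 probe sets were called in dcl4-2 leaf, with 652 at an unadjusted p under 0.05 and a smallest adjusted p of 0.238. In these 5 groups 0 members were called, with 0 auxin-responsive, 0 autophagy, 2 defence, 1 plastid and 0 anther genes at an unadjusted p under 0.05. Without dcl4-2 leaf replicate 2 the count was 3, with array weights it was 3, and in a fit of all 27 arrays it was 19. The 12 leaf arrays of all genotypes had a 3' minus 5' difference of 2.59 to 4.16, above most inflorescence arrays (0.72 to 1.17). Its effect on the leaf counts was not tested. Leaving out 1 array ended each list call: Col-0 replicate 3 (adjusted p = 0.167) or dcl4-2 replicate 2 (0.143) for auxin-responsive genes, Col-0 replicate 1 (0.501), dcl4-2 replicate 2 (0.0502) or dcl4-2 replicate 3 (0.238) for autophagy, Col-0 replicate 3 (0.0785) for defence, Col-0 replicate 2 (0.123) or dcl4-2 replicate 1 (0.0571) for plastid transcripts, and Col-0 replicate 2 (0.0519), Col-0 replicate 3 (0.21) or dcl4-2 replicate 2 (0.438) for anther genes.

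The leaf of rdr6-15, which lacks the polymerase of the same pathway, had 1 named gene past the threshold. QQS rose by 2.16 (SE 0.18, adjusted p = 0.0012), from 8.03 ± 0.24 in Col-0 to 10.20 ± 0.08. The other calls were probe sets without a gene name. Of these, 2 rose, by 1.84 (SE 0.21, adjusted p = 0.016) and by 1.76 (SE 0.21, adjusted p = 0.019), and 1 fell by 1.19 (SE 0.15, adjusted p = 0.019). AT1G12775 differed by 0.95 (SE 0.18, adjusted p = 0.49), at 6.15 ± 0.35. Plastid transcripts lay higher as a group, 51 of 66 of them, with a median of 0.38 (adjusted p = 1.26e-08, and adjusted p = 0.629 with an estimated correlation). All 10 autophagy genes lay higher. The median was 0.23 (adjusted p = 0.000547, and adjusted p = 0.594 with an estimated correlation). The 3 auxin-responsive genes lay higher too. The median was 0.45 (adjusted p = 0.00776, and adjusted p = 0.324 with an estimated correlation). WES1 among them was at 0.36 (SE 0.12, adjusted p = 1), the 1 of 3 past the threshold adjusted over the list alone. The 10 flavonoid genes of the wider list lay lower by a median of −0.12 (adjusted p = 0.0459, and adjusted p = 0.426 with an estimated correlation). With each array centred on its median this list did not pass (adjusted p = 0.0621). In these 4 groups limma called 0 members, with 12 plastid, 1 autophagy, 1 auxin-responsive and 0 flavonoid genes at an unadjusted p under 0.05. In all, 3 probe sets rose and 1 fell, with 773 at an unadjusted p under 0.05. The 4 calls became 1 without Col-0 leaf replicate 2, Col-0 leaf replicate 3 or rdr6-15 leaf replicate 3, and 2 without Col-0 leaf replicate 1 or rdr6-15 leaf replicate 2. Here too leaving out 1 array ended each list call: rdr6-15 replicate 2 for plastid transcripts (median 0.02, adjusted p = 0.549), Col-0 replicate 1 (adjusted p = 0.103) or rdr6-15 replicate 3 (0.213) for autophagy, Col-0 replicate 3 (0.0954) or rdr6-15 replicate 1 (0.178) for auxin-responsive genes, and Col-0 replicate 1 (0.195), Col-0 replicate 2 (0.204), rdr6-15 replicate 1 (0.0782) or rdr6-15 replicate 3 (0.266) for flavonoid genes.

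In the leaf of dcl1-7, where microRNA production is impaired, several of the known microRNA targets with a named probe set rose. Of 10 measured targets 6 rose, and 6 adjusted over the list alone, with a median of 0.64 (adjusted p = 0.000304, and adjusted p = 0.17 with an estimated correlation). They include PHV, a leaf polarity gene targeted by miR166, which rose by 0.99 (SE 0.13, adjusted p = 0.0013), and AGL16, a MADS-box gene targeted by miR824, which rose by 1.02 (SE 0.15, adjusted p = 0.0019) from 8.79 ± 0.25 to 9.81 ± 0.21. CCS, the copper chaperone of superoxide dismutase and a target of miR398, rose by 1.18 (SE 0.20), and APS4, an ATP sulfurylase targeted by miR395, by 1.12 (SE 0.20). APS3 and ARPN were the other 2 targets called. AT1G12775 rose by 1.22 (SE 0.18, adjusted p = 0.0019), the only called gene of 15 RFL genes (list adjusted p = 0.825). QQS, named after its values were seen, fell by 1.37 (SE 0.18, adjusted p = 0.00113) to 6.67 ± 0.25.

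Cold and abscisic acid response genes rose in dcl1-7 leaf. The 3 measured genes of the first cold list all rose, also adjusted over the list alone. The median was 1.67 (adjusted p = 0.000561, and adjusted p = 0.324 with an estimated correlation). COR47 rose by 2.27 (SE 0.29), COR15A by 1.67 (SE 0.37) and COR15B by 1.64 (SE 0.27). These 3 are also in the wider cold list, of which 5 of 9 rose, and 6 adjusted over the list alone. The median was 0.51 (adjusted p = 0.000184, and adjusted p = 0.196 with an estimated correlation). Among 13 jasmonate response genes 5 rose, and 6 adjusted over the list alone. The median was 0.50 (adjusted p = 0.0113, and adjusted p = 0.324 with an estimated correlation). They include JRG21, an oxidase that inactivates jasmonate (2.03, SE 0.19), the jacalin-related lectins JAL23 (1.62, SE 0.29) and JAL34 (0.72, SE 0.12), and the defensin PDF1.2b (1.75, SE 0.37), whose near-identical relatives may share its probes. The list did not pass without dcl1-7 replicate 1 (adjusted p = 0.0554). PDF1.2 itself, 1 of 2 measured genes of the shorter jasmonate list and also in the wider one, rose by 1.46 (SE 0.36, adjusted p = 0.024). All 10 autophagy genes lay higher, of which 3 rose, and 5 adjusted over the list alone. The median was 0.45 (adjusted p = 0.00085, and adjusted p = 0.606 with an estimated correlation). ATG8B rose by 0.93 (SE 0.19), ATG8G by 0.80 (SE 0.17) and ATG8F by 0.72 (SE 0.13).

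Of 28 nuclear photosynthesis genes 6 fell and 1 rose in dcl1-7 leaf, and 11 fell and 1 rose adjusted over the list alone. The median was −0.10 (adjusted p = 0.00578, and adjusted p = 0.629 with an estimated correlation). LHCB4.3, a light-harvesting protein, fell by 1.19 (SE 0.11). The chlorophyll and heme synthesis genes HEME2 and HEME1 were at −1.01 (SE 0.16) and −0.93 (SE 0.18), and CHLI2, a magnesium chelatase subunit, at −0.69 (SE 0.13). Plastid transcripts went both ways. atpB, a subunit of ATP synthase, fell by 2.74 (SE 0.65) and the ribosomal protein rpl33 fell by 0.77 (SE 0.17). psbA, a photosystem II core protein, rose by 0.80 (SE 0.18). Over the 66 plastid transcripts 2 rose and 6 fell, 3 and 6 adjusted over the list alone, yet 49 lay higher. The median was 0.48 (adjusted p = 0.0362, and adjusted p = 0.859 with an estimated correlation). This list did not pass without Col-0 replicate 1 (adjusted p = 0.0844), Col-0 replicate 3 (0.102), dcl1-7 replicate 2 (0.264) or dcl1-7 replicate 3 (0.0678). Of 16 mitochondrial transcripts 3 rose, and 4 adjusted over the list alone, among them ccb452 by 0.65 (SE 0.14), with a list median of 0.23 (adjusted p = 0.00398, and adjusted p = 0.557 with an estimated correlation). Of 8 cytokinin genes 1 rose, and 2 adjusted over the list alone. The median was 0.22 (adjusted p = 0.0391, and adjusted p = 0.324 with an estimated correlation). It was UGT76C2, a cytokinin glucosyltransferase, at 0.84 (SE 0.20). The list did not pass without Col-0 replicate 2 (adjusted p = 0.107) or dcl1-7 replicate 3 (0.0534). YAB5, 1 of 2 measured leaf polarity genes of that list, rose by 0.45 (SE 0.12, adjusted p = 0.038).

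The largest rises in dcl1-7 leaf were those of AT5G05600, a jasmonate oxidase (3.15, SE 0.67), AT1G52000, a jacalin-related lectin (2.96, SE 0.30), the dehydrin LTI30 (2.64, SE 0.38) and AT4G12490 (2.62, SE 0.47). AT1G02300, a cathepsin B-like protease (2.62, SE 0.22), and the expansin-like EXLA1 (2.57, SE 0.30) followed. After atpB the largest falls were those of AT2G33850 (−2.57, SE 0.25), AT3G44400, a resistance protein of the TIR class (−2.38, SE 0.44), AT5G45670, a GDSL lipase (−1.91, SE 0.17), AT5G62210 (−1.59, SE 0.24) and AT5G07030 (−1.48, SE 0.37). The adjusted p of these 12 genes ran from 0.00013 to 0.026. In all 951 probe sets rose and 1191 fell, 223 and 148 of them at least 2-fold, and 5414 were at an unadjusted p under 0.05. The 3' minus 5' difference of the control transcripts, which grows as RNA degrades, was 3.63 ± 0.48 in dcl1-7 leaf and 3.0 ± 0.41 in Col-0 leaf, with overlapping ranges (3.22 to 4.16 and 2.62 to 3.44). The 2142 calls became 1043 without Col-0 leaf replicate 1, 1154 without Col-0 leaf replicate 2, 3842 without dcl1-7 leaf replicate 1, 1336 without dcl1-7 leaf replicate 2 and 1190 without dcl1-7 leaf replicate 3.

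**Figure D2:**
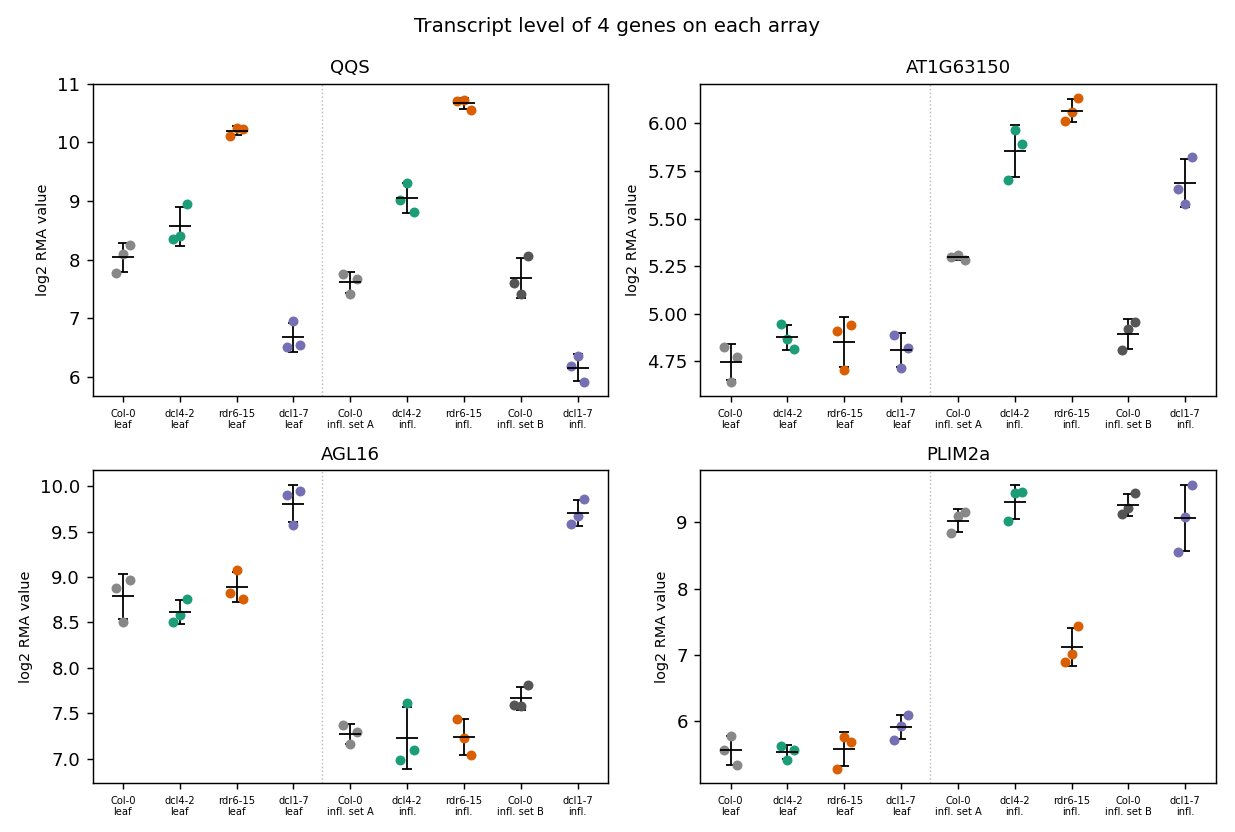
Transcript level (log2 RMA value, vertical axis) of QQS, AT1G63150, AGL16 and PLIM2a on each of the 27 arrays by group (horizontal axis); points are arrays, and bars are the mean ± SD of n = 3. QQS lies at 10.20 and 10.67 in rdr6-15 leaf and inflorescence and at 6.67 and 6.15 in dcl1-7, AT1G63150 is raised in the inflorescence of each mutant, AGL16 is raised in dcl1-7 in both tissues, and PLIM2a is lower in rdr6-15 inflorescence (7.11 against 9.02 in Col-0 set A).

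Set against Col-0 set A, dcl4-2 inflorescences had changes in QQS, in a defensin-like gene and in several small gene groups. QQS rose by 1.44 (SE 0.17, adjusted p = 0.0017), from 7.61 ± 0.18 to 9.04 ± 0.25, and AT3G05730, the defensin-like gene, fell by 3.45 (SE 0.34, adjusted p = 0.00063), from 8.13 ± 0.49 to 4.68 ± 0.13. AT1G63150, another RFL pentatricopeptide repeat gene, rose by 0.56 (SE 0.08, adjusted p = 0.0045), from 5.30 ± 0.01 to 5.85 ± 0.14. AT1G12775 (0.52, SE 0.14, adjusted p = 0.092) and AT1G12620 (0.47, SE 0.15, adjusted p = 0.14) missed the threshold. Of 15 RFL genes 1 rose, and 3 adjusted over the list alone, with a median of 0.01 and a mean of 0.14 (adjusted p = 0.0191, adjusted p = 0.461 with an estimated correlation, and adjusted p = 0.0575 without dcl4-2 replicate 3). Members of this family are similar in sequence, so their probes may share signal.

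Cold response genes rose in dcl4-2 inflorescence: COR15B by 0.95 (SE 0.18, adjusted p = 0.017) and COR15A by 0.74 (SE 0.12, adjusted p = 0.0083), with COR47 at 0.68 (SE 0.19, adjusted p = 0.091). These are 2 of 3 measured genes, and 3 adjusted over the list alone. The median was 0.74 (adjusted p = 7.42e-05, and adjusted p = 0.221 with an estimated correlation). In the wider cold list, which holds the same 3 genes, 2 of 9 rose and XERICO fell by 0.42 (SE 0.08). Adjusted over the list alone these were 4 and 1. The median was 0.17 (adjusted p = 0.0362, and adjusted p = 0.592 with an estimated correlation). This list did not pass without the most weakly expressed probe sets (adjusted p = 0.0634), or without set A replicate 1 (0.0732), set A replicate 2 (0.11) or dcl4-2 replicate 3 (0.234). Of 11 tau glutathione transferases 2 rose, GSTU26 by 0.84 (SE 0.14) and GSTU27 by 0.49 (SE 0.10). The median was 0.09 (adjusted p = 0.0119, and adjusted p = 0.23 with an estimated correlation). LEA, the 1 gene of 8 in the wider seed storage list that rose, did so by 0.96 (SE 0.21). The median was 0.25 (adjusted p = 0.0119, adjusted p = 0.324 with an estimated correlation, and adjusted p = 0.0669 without dcl4-2 replicate 3). WES1, an enzyme that conjugates auxin to amino acids, fell by 0.60 (SE 0.09, adjusted p = 0.0065). It was the 1 called gene of 20 in the wider auxin list, and 2 fell adjusted over the list alone. The median was −0.08 (adjusted p = 0.0119, and adjusted p = 0.412 with an estimated correlation). Without dcl4-2 replicate 2 and 2 other arrays of high 3' minus 5' difference this list no longer passed (median −0.06, adjusted p = 0.0642). LHCB4.2 fell by 0.34 (SE 0.07), 1 of 28 nuclear photosynthesis genes. The median was −0.09 (adjusted p = 0.0266, and adjusted p = 0.662 with an estimated correlation). This list did not pass without set A replicate 2 (adjusted p = 0.062), set A replicate 3 (0.0705) or dcl4-2 replicate 1 (0.0732). Plastid transcripts lay lower in 53 of 66 cases. The median was −0.31 (adjusted p = 0.0044, and adjusted p = 0.751 with an estimated correlation). Of them 0 were called by limma and 1 was at an unadjusted p under 0.05. The 3' minus 5' difference was 2.36 on dcl4-2 inflorescence replicate 2 and 0.91 and 0.86 on the other replicates. The plastid median was −0.23 (adjusted p = 2.34e-06) without this array and 2 others, and −0.27 (adjusted p = 0.12) without dcl4-2 replicate 1. The microRNA target list did not pass (adjusted p = 0.584), and 1 of 10 targets was called, CCS, which fell by 0.63 (SE 0.13).

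Besides QQS, the largest rises in dcl4-2 inflorescence were those of AT5G62360, a pectin methylesterase inhibitor (1.40, SE 0.18), AT3G62550 (1.23, SE 0.28), AT2G34700 (1.2, SE 0.10), EXO, a brassinosteroid-responsive gene (1.18, SE 0.25), and AT5G62730 (1.11, SE 0.15). After AT3G05730 the largest falls were those of AT3G15450 (−1.60, SE 0.12), AT5G19120 (−1.45, SE 0.18), AT2G20670 (−1.34, SE 0.17), the senescence regulator WRKY53 (−1.33, SE 0.22) and AT1G55450 (−1.30, SE 0.21). Their adjusted p ran from 0.00012 to 0.039. In all 252 probe sets rose and 221 fell (264 and 267 after quantile normalization), 12 and 32 of them at least 2-fold, with 3126 at an unadjusted p under 0.05. The 473 calls became 70 higher and 87 lower ones without Col-0 set A replicate 1, and in number 213 without set A replicate 2, 213 without set A replicate 3, 267 without dcl4-2 replicate 1, and 253 without dcl4-2 replicate 2. Without the 3 arrays of high 3' minus 5' difference, a setting added after seeing the data, there were 916. The effect in inflorescence differed from that in leaf by test for AT3G05730 (−3.56, adjusted p = 0.00025), WES1 (−0.78, adjusted p = 0.023) and XERICO (−0.95, adjusted p = 0.028). The test was not passed for QQS (0.90, SE 0.26, adjusted p = 0.21), AT1G63150 (0.43, adjusted p = 0.19), COR15A (1.51, adjusted p = 0.17) or COR15B (1.5, adjusted p = 0.075). With set B as control, EXO (−1.33), AT3G62550 (−0.50) and COR47 (−0.23) had the opposite sign.

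In the inflorescence of rdr6-15, transcripts known from pollen fell. Of 22 pollen genes 9 fell, also adjusted over the list alone, and 18 lay lower, with a median of −0.16 and a mean of −0.45 (adjusted p = 6.66e-07, and adjusted p = 0.182 with an estimated correlation). PLIM2a, a pollen actin-binding protein, fell by 1.91 (SE 0.22, adjusted p = 0.00036), from 9.02 ± 0.17 to 7.11 ± 0.28. The pollen pectate lyase AT59 was at −2.20 (SE 0.28), the alpha-tubulin TUA1 at −0.68 (SE 0.09) and the pollen actin ACT12 at −0.64 (SE 0.10). Of 14 SWEET sugar transporters 6 fell, and 7 adjusted over the list alone. The median was −0.39 (adjusted p = 2.23e-05, and adjusted p = 0.324 with an estimated correlation). The nectary transporter SWEET9 was at −2.21 (SE 0.27), SWEET13 at −0.89 (SE 0.15), SWEET8, which acts in the anther, at −0.67 (SE 0.13) and SWEET7 at −0.45 (SE 0.11). SWEET8 is also in the wider tapetum list, where it was the 1 called gene of 10. The median was −0.28 (adjusted p = 0.028, and adjusted p = 0.461 with an estimated correlation). This list did not pass without set A replicate 2 (adjusted p = 0.0537) or rdr6-15 replicate 1 (0.24). The tissue difference passed for PLIM2a (−1.93, SE 0.28, adjusted p = 0.00046), AT59 (−2.22), ACT12 (−0.69), SWEET9 (−2.10) and SWEET8 (−1.21). It was not passed for TUA1 (−0.57, adjusted p = 0.21), SWEET13 (−0.92, adjusted p = 0.16) or SWEET7 (−0.48, adjusted p = 0.18).

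QQS rose by 3.06 in rdr6-15 inflorescence (SE 0.17, adjusted p = 6.1e-06) to 10.67 ± 0.09, and its tissue difference was 0.89 (SE 0.26, adjusted p = 0.071). AT1G63150 rose by 0.77 (SE 0.08, adjusted p = 0.00019) to 6.07 ± 0.06, which differed from the leaf effect by 0.67 (SE 0.12, adjusted p = 0.0027). In leaf AT1G63150 lay below the lower quartile of the arrays, at 4.75 ± 0.10 in Col-0 and 4.85 ± 0.13 in rdr6-15. RMA compresses differences there, so a leaf effect could be missed. The inflorescence level in set A (5.30 ± 0.01) also lay below the lower quartile of its arrays (5.434 to 5.494), so this limit is not particular to leaf. AT1G63150 was the 1 called gene of 15 RFL genes, with 3 adjusted over the list alone and 13 higher. The median was 0.15 (adjusted p = 0.00365, and adjusted p = 0.324 with an estimated correlation). AT1G12775 was at 0.49 (SE 0.14, adjusted p = 0.053). Of 28 nuclear photosynthesis genes 5 rose, and 7 adjusted over the list alone. The median was 0.17 (adjusted p = 0.000619, and adjusted p = 0.489 with an estimated correlation). The chlorophyll synthesis genes PORB, CHLI2 and CHLM rose by 1.19 (SE 0.17), 0.58 (SE 0.11) and 0.24 (SE 0.06), and the photosystem II assembly gene PAM68 by 0.45 (SE 0.08). SPCH, which starts the stomatal lineage, rose by 0.48 (SE 0.10), 1 of 4 stomatal genes, and 4 of 4 adjusted over the list alone. The median was 0.30 (adjusted p = 0.0103, and adjusted p = 0.287 with an estimated correlation). Without the most weakly expressed probe sets the adjusted p was 0.0503. Of 20 auxin genes 4 fell, among them the auxin-conjugating enzymes GH3.17 (−0.87, SE 0.14) and WES1 (−0.50, SE 0.09). The list had a median of −0.03 and a mean of −0.11 (adjusted p = 0.0266, adjusted p = 0.465 with an estimated correlation, and adjusted p = 0.0908 without rdr6-15 replicate 2). All 10 autophagy genes lay lower. The median was −0.15 (adjusted p = 0.0103, adjusted p = 0.619 with an estimated correlation, and adjusted p = 0.0705 without set A replicate 3). Of them 0 were called by limma and 3 were at an unadjusted p under 0.05. The thionin THI2.1, 1 of 2 measured genes of the shorter jasmonate list, fell by 0.98 (SE 0.14, adjusted p = 0.00096). The microRNA target list did not pass (adjusted p = 0.332), with 2 of 10 members that fell.

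The largest rises in rdr6-15 inflorescence after QQS were those of AT1G22890 (1.84, SE 0.18), AT5G61590, an ERF transcription factor (1.73, SE 0.14), AT4G30650 (1.61, SE 0.32), LTI30 (1.47, SE 0.34) and AT2G39400 (1.35, SE 0.20). The largest falls were those of the cytochrome P450 gene CYP71B31 (−3.45, SE 0.37), AT5G39880 (−2.80, SE 0.28), the protease inhibitor AT1G72290 (−2.67, SE 0.21), AT5G26700, a germin-like gene (−2.37, SE 0.20), the signalling peptide RALFL25 (−2.28, SE 0.30) and AT3G26860 (−2.24, SE 0.33). The adjusted p of these genes ran from 3.1e-05 to 0.017. In all 948 probe sets rose and 1021 fell (1051 and 999 with each array centred on its median), 32 and 253 of them at least 2-fold, with 5009 at an unadjusted p under 0.05. The 1969 calls became 1121 without Col-0 set A replicate 1, 1222 without set A replicate 2, 1079 without set A replicate 3, 1273 without rdr6-15 replicate 1 and 1035 without rdr6-15 replicate 2. They were 4476 in a fit of only the 2 groups compared, 5254 with array weights and 1253 in a fit of all 27 arrays. The 1969 calls rest on a spread from all 15 inflorescence arrays, the 3 of high 3' minus 5' difference included. Those 3 arrays are not in the groups compared here, so this spread may exceed that of these groups. No fit of this comparison without them was run. With set B as control, AT1G22890 (−3.64), AT2G39400 (−1.38), AT5G61590 (−0.73), PAM68 (−0.35), CHLM (−0.17), CYP71B31 (0.08), AT1G72290 (0.31), SWEET7 (1.72) and THI2.1 (2.05) had the opposite sign. The 3' minus 5' difference was 0.80 ± 0.07 in rdr6-15 and 0.98 ± 0.03 in set A.

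Against their Col-0 set B, dcl1-7 inflorescences had higher levels of several of the measured microRNA targets. Of 10 targets 6 rose, and 7 adjusted over the list alone. The median was 0.53 (adjusted p = 0.000619, and adjusted p = 0.17 with an estimated correlation). AGL16 rose by 2.04 (SE 0.15, adjusted p = 1.1e-06), at 9.71 ± 0.14 against 7.66 ± 0.13 in set B and 7.27 ± 0.11 in set A, more than in leaf by 1.02 (SE 0.22, adjusted p = 0.0016). ARPN, a small blue copper protein targeted by miR408, rose by 1.39 (SE 0.10), APS4 by 0.92 (SE 0.17) and APS3 by 0.58 (SE 0.09). Their tissue differences were 0.59 (adjusted p = 0.087), −0.20 (adjusted p = 0.66) and 0.11 (adjusted p = 0.66). With set A as control, the difference was 1.41 for AGL16, −0.38 (adjusted p = 0.31) for ARPN and −0.67 (adjusted p = 0.0034) for APS3. Against set A, a comparison added after seeing the data, 4 of the 10 rose (median 0.16; adjusted p = 0.0881). AGL16 was at 2.43, APS4 at 0.94, ARPN at 0.42 and APS3 at −0.20. AT1G63150 rose by 0.79 (SE 0.08, adjusted p = 1.4e-05), from 4.89 ± 0.08 to 5.69 ± 0.13, more than in leaf by 0.73 (adjusted p = 0.00011). Its leaf signal was weak, at 4.75 ± 0.10 in Col-0 and 4.81 ± 0.09 in dcl1-7, where a change could be missed. The rise of 0.79 was called from a set B level that also lay below the lower quartile of its arrays (5.434 to 5.485). Weak signal thus limits both tissues. Against set A AT1G63150 was at 0.39, with a tissue difference of 0.33 (adjusted p = 0.065). It was 1 of the 3 RFL genes, of 15, that rose, also 3 adjusted over the list alone. The median was 0.04 (adjusted p = 0.0397, and adjusted p = 0.557 with an estimated correlation). Against set A the RFL list did not pass, with 1 gene higher and 1 lower (median 0.02, adjusted p = 0.879). Nor did it pass with each array centred on its median (adjusted p = 0.0613), or without set B replicate 1 (0.0907), set B replicate 3 (0.0594) or dcl1-7 replicate 1 (0.066). QQS, named after its values were seen, was at −1.54 against set B and −1.46 against set A, with a level of 6.15 ± 0.23. Its tissue difference was −0.17 (adjusted p = 0.7).

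Several other groups moved against set B, and of these the autophagy, cell division and flavonoid genes moved the other way against set A. Of 10 autophagy genes 6 fell, and 9 adjusted over the list alone. The median was −0.40 (adjusted p = 5.63e-05, and adjusted p = 0.412 with an estimated correlation). ATG8H was at −1.53, ATG8E at −0.75 and APG8A at −0.68. All 10 rose against set A. The median was 0.96 (adjusted p = 1.02e-07, and adjusted p = 0.362 with an estimated correlation). The 3 cell division genes rose, also adjusted over the list alone. The median was 0.68 (adjusted p = 0.00625, and adjusted p = 0.387 with an estimated correlation). The replication gene PRL was at 1.07 (SE 0.19) and the Aurora kinases AUR1 and AUR2 at 0.68 (SE 0.09) and 0.64 (SE 0.15). All 3 fell against set A. The median was −1.11 (adjusted p = 0.0044, and adjusted p = 0.362 with an estimated correlation). Of 21 defence genes 11 fell and 1 rose, 12 and 1 adjusted over the list alone. The median was −0.40 (adjusted p = 5.63e-05, and adjusted p = 0.396 with an estimated correlation). Against set A 5 rose and 2 fell, and the list did not pass (median 0.05, adjusted p = 0.65). The calcium sensors CML41 and CML37 were at −1.75 (SE 0.17) and −0.89 (SE 0.10), UGT76B1 at −1.69 (SE 0.12) and WRKY6 at −0.92 (SE 0.07). Against set A, CML41 (−0.01), CML37 (0.05) and WRKY6 (−0.13) were not called, and UGT76B1 was called in the opposite direction (0.37, adjusted p = 0.026). WRKY53, named outside the rule, was at −1.64 (SE 0.22, adjusted p = 0.00016) and against set A at −1.02 (adjusted p = 0.0029). WES1 fell by 0.77 (SE 0.09) as 1 of the 2 auxin-responsive genes, of 3, that fell. The median was −0.77 (adjusted p = 0.0362, and adjusted p = 0.324 with an estimated correlation). Against set A it was at 2.28, and the list did not pass (median −0.04, mean 0.59, adjusted p = 0.556). Nor did it pass against set B without set B replicate 1 (adjusted p = 0.0787) or dcl1-7 replicate 2 (0.06). CHIL, a chalcone isomerase-like gene, rose by 0.92 (SE 0.11) as 1 of the 3 flavonoid genes, of 10, that rose. The median was 0.18 (adjusted p = 0.0113, and adjusted p = 0.324 with an estimated correlation). Its change against set A was −1.12, and 5 of the 10 fell. The median there was −0.29 (adjusted p = 0.0416, and adjusted p = 0.463 with an estimated correlation).

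Of 13 jasmonate response genes 5 rose in dcl1-7 inflorescence, also 5 adjusted over the list alone, with a median of 0.19 and a mean of 0.76 (adjusted p = 0.0135, and adjusted p = 0.412 with an estimated correlation). Against set A 6 rose and 1 fell, and the list did not pass (median 0.41, adjusted p = 0.164). Nor did it pass against set B without set B replicate 1 (adjusted p = 0.0626) or dcl1-7 replicate 2 (0.0668). JAL23 rose by 4.07 (SE 0.23) and by 0.69 against set A (adjusted p = 0.031), and THI2.1 rose by 2.64 (SE 0.14) and was at −0.38 against set A. The jasmonate methyltransferase JMT rose by 1.27 (SE 0.22) and was at −0.53, and the transcription factor MYC4 rose by 0.49 (SE 0.12) and was at 0.41. PDF1.2 rose by 0.77 (SE 0.23) and by 1.26 against set A. It and THI2.1 are the 2 measured genes of the shorter jasmonate list and stand in both lists. Of 10 heat response genes 5 fell, and 6 adjusted over the list alone. The median was −0.28 (adjusted p = 0.0103, and adjusted p = 0.221 with an estimated correlation). The chaperone genes Fes1A and Hsp70-2 were at −0.92 (SE 0.11) and −0.79 (SE 0.09). Against set A 1 heat gene rose and 3 fell, and the list did not pass (median −0.03, adjusted p = 0.556), with Fes1A at −0.02 and Hsp70-2 at −0.98. Of 28 nuclear photosynthesis genes 7 rose, among them SBPASE of the Calvin cycle by 0.66 (SE 0.08), which was at −0.14 against set A (adjusted p = 0.19). The median was 0.10 (adjusted p = 0.0257, and adjusted p = 0.662 with an estimated correlation). Without the 3 arrays of high 3' minus 5' difference the adjusted p was 0.111, and against set A it was 0.502 (median 0.05, 11 higher and 5 lower). It was 0.0909 without the most weakly expressed probe sets, 0.0933 without set B replicate 3 and 0.14 without dcl1-7 replicate 1. In lists of 1 or 2 measured genes, AGO7, an ARGONAUTE of the trans-acting siRNA pathway, rose by 0.51 (SE 0.11). The ovule gene INO was at −1.06 (SE 0.14), the carpel gene SPT at −0.42 (SE 0.10) and the defence gene SAG101 at −0.61 (SE 0.16), all called. Against set A, SPT (0.77, adjusted p = 5.6e-05) and SAG101 (0.45, adjusted p = 0.043) were called in the opposite direction, and AGO7 (−0.15) and INO (−0.33, adjusted p = 0.085) were not called.

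The largest rises against set B were those of AT1G54020, a GDSL lipase (4.2, SE 0.22, and 0.58 with adjusted p = 0.061 against set A), JAL23, CYP71B31 (2.95, SE 0.37), AT5G62210 (2.89, SE 0.12), AT5G52390 (2.69, SE 0.21) and the thiol reductase GILT (2.68, SE 0.30). The largest falls were those of AT1G21520 (−3.09, SE 0.14), the chitinase family gene AT2G43570, whose symbol here is CHI (−3.08, SE 0.14), AT5G52760 (−3.05, SE 0.19), AT1G09500 (−3.04, SE 0.31), AT3G60420 (−2.96, SE 0.13) and AT1G05340 (−2.94, SE 0.27). Of these 12 genes AT1G54020 and JAL23 kept their sign against set A, and the other 10 had the opposite sign. Among the latter, CYP71B31 (−0.58, adjusted p = 0.27), AT1G21520 (0.35, adjusted p = 0.069), CHI (0.25, adjusted p = 0.18) and AT5G52760 (0.29, adjusted p = 0.28) were not called there. In all 2859 probe sets rose and 2455 fell against set B (2507 and 2885 with each array centred on its median), 308 and 346 of them at least 2-fold, with 7417 at an unadjusted p under 0.05, against 3901 and 4109 with set A. Only 542 probe sets were called in the same direction against both sets, 391 higher and 151 lower (490 and 443 if the lists were independent), and 2734 in opposite directions. The 3' minus 5' difference was 2.48 on dcl1-7 inflorescence replicate 3 and 2.59 on set B replicate 3, and from 0.84 to 1.17 on the other arrays of these groups. AT5G52790 (2.13 and 2.24), AGL16, APS4, QQS and WRKY53 moved alike against both sets. AT5G52790 was named after its values were seen.

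**Figure D3:**
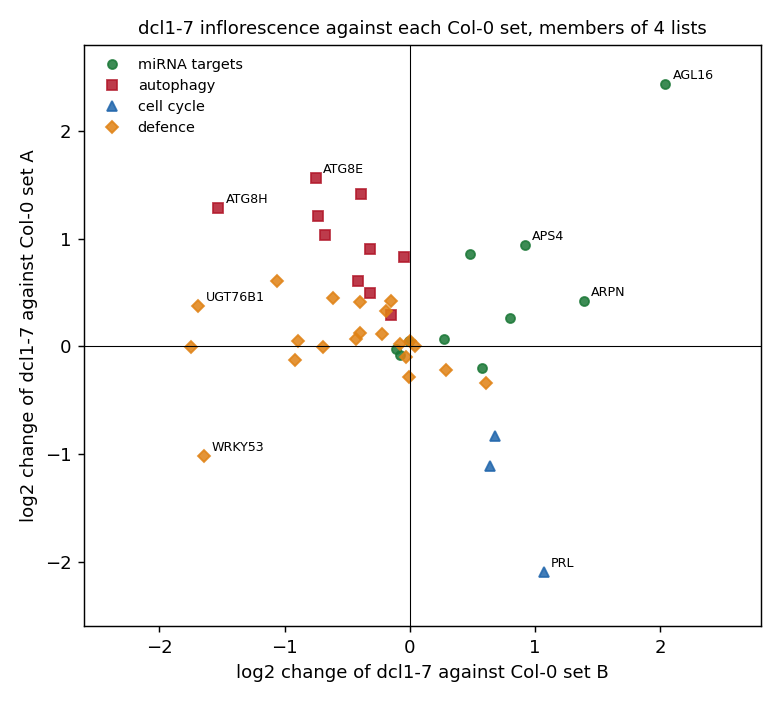
Log2 change in dcl1-7 inflorescence against Col-0 set B (horizontal axis) and against set A (vertical axis); points are single genes of the microRNA target, autophagy, cell division and defence lists. AGL16 (2.04 and 2.43) and APS4 (0.92 and 0.94) are high on both axes, while the autophagy genes (median −0.40 and 0.96) and the cell division genes (median 0.68 and −1.11) lie in opposite quadrants.

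The Col-0 inflorescence sets, both wild type, differed from each other in 10847 probe sets, more than any of the mutants from its labelled control. Set B had higher levels of AT1G12010 (6.89, SE 0.14), the drought-inducible linker histone HIS1-3 (6.46, SE 0.17) and the vicilin-like storage protein gene PAP85 (6.27, SE 0.13), and lower levels of AT5G62210 (−5.52, SE 0.12), the plastid ATP synthase gene atpH (−4.38, SE 0.25) and the thaumatin-like ATLP-1 (−4.14, SE 0.19). All 10 autophagy genes were higher in set B (median 1.47), as were 13 of 21 defence genes, with 3 lower (median 0.52), and 4 of 9 cold genes of the wider list, with 2 lower (median 0.54). The first cold list went the other way, with 2 of its 3 genes lower in set B and 1 higher (median −1.07). The 3 cell division genes (median −1.75), 36 of 66 plastid transcripts (median −0.77), 7 of 10 flavonoid genes (median −0.51), 6 of 10 meiosis genes (median −0.28) and 5 of 10 tapetum genes, with 1 higher (median −0.60), were lower. QQS, named outside the rule, differed by 0.08 (adjusted p = 0.765). In all 5151 probe sets were higher and 5696 lower, 47.7% of the 22746, and 1556 and 1466 of them at least 2-fold. The arrays of set A correlated with those of set B at 0.928 to 0.933, below the correlation of dcl1-7 with set A (0.959 to 0.974) or set B (0.968 to 0.981). Set B replicate 3 had a 3' minus 5' difference of 2.59, and the count was 10546 without it.

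**Figure D4:**
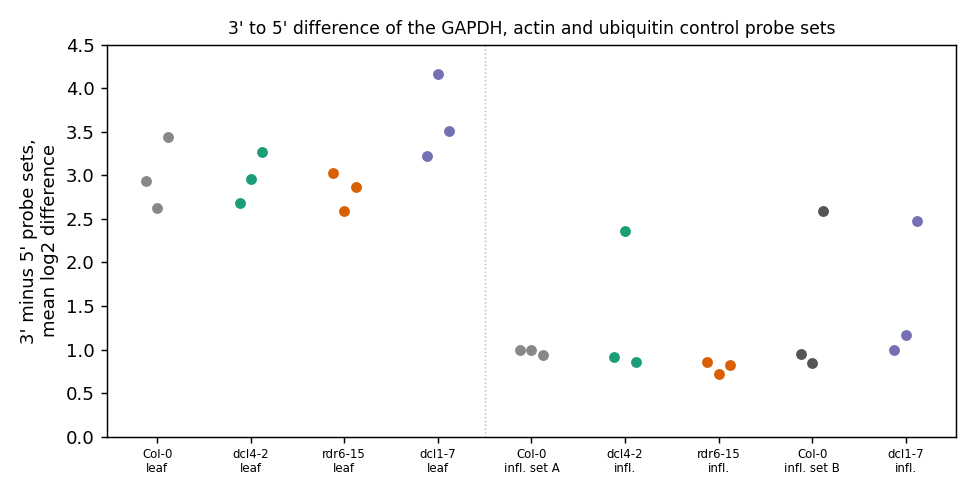
Mean log2 difference between the 3' and 5' probe sets of the GAPDH, actin and ubiquitin controls (vertical axis) on each of the 27 arrays, by group (horizontal axis); each point is an array. Leaf arrays lie between 2.59 and 4.16, and inflorescence arrays between 0.72 and 1.17 except dcl4-2 replicate 2 (2.36), Col-0 set B replicate 3 (2.59) and dcl1-7 replicate 3 (2.48).

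The direct comparison of dcl4-2 with rdr6-15 asks whether mutants of the same pathway differ. In leaf, QQS was lower in dcl4-2 by −1.63 (SE 0.18, adjusted p = 0.024), and 2 probe sets without a gene name were the only other calls of limma, at −1.70 (SE 0.21) and 1.04 (SE 0.12). At an unadjusted p under 0.05 there were 1097. The 3 calls became 0 without dcl4-2 leaf replicate 1 or rdr6-15 leaf replicate 2, and 1 without dcl4-2 leaf replicate 3 or rdr6-15 leaf replicate 3. In inflorescence CYP71B31 (4.66, SE 0.37), AT5G39880 (3.05, SE 0.28) and RALFL25 (2.72, SE 0.30) were higher in dcl4-2, and AT3G05730 (−4.79, SE 0.34), the thionin family gene AT1G66100 (−2.57, SE 0.38) and AT1G22890 (−2.28, SE 0.18) lower. QQS, named outside the rule, was lower too (−1.62, SE 0.17). There 1825 probe sets were higher in dcl4-2 and 1688 lower (1781 and 1817 with each array centred on its median), 400 and 80 of them at least 2-fold. The 3513 calls became 2320 without rdr6-15 inflorescence replicate 2.

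Genes called in both mutants in inflorescence included QQS, AT1G63150, COR15B (0.95 in dcl4-2 and 0.87 in rdr6-15), EXO (1.18 and 1.14), AT5G62360 (1.40 and 0.83) and AT5G61590 (0.86 and 1.73) among those that rose. WRKY53 (−1.33 and −0.92), the ubiquitin ligase PUB19 (−0.90 and −0.90) and AT1G48100 (−0.78 and −1.21) fell in both. In opposite directions went AT3G05730 (−3.45 and 1.34), AT1G75300 (0.91 and −0.93) and ZW9 (−0.78 and 1.03). The genes of this paragraph outside the rule were chosen after their values were seen. Of probe sets, 46 rose in both (10.5 if the lists were independent), 78 fell in both (9.92) and 30 went opposite ways. Across probe sets the log2 changes correlated at 0.013, where simulated unchanged groups with a shared simulated control gave 0.502. The simulation gives all its groups the same spread, so this value was fixed in advance. That spread comes from all 15 inflorescence arrays, the 3 of high 3' minus 5' difference included. It may exceed the spread of set A, whose arrays correlated at 0.9973 to 0.9978. The simulated values therefore cannot show whether the mutants are more or less alike than unchanged groups. The covariance was 0.000718 against a simulated 0.01, and the correlation was 0.043 with rdr6-15 set against Col-0 set B. With these separate controls 133 probe sets rose in both (69.9 if independent), 138 fell in both (54.3) and 112 went opposite ways. In leaf the correlation was 0.354 (simulated 0.499), with a covariance of 0.00906 (simulated 0.0163). Part of the overlaps may come from the shared controls.

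In dcl1-7 the leaf and inflorescence changes correlated at −0.122 across probe sets with set B as control and at 0.356 with set A. With set B, 188 probe sets rose in both tissues (120 if independent), 51 fell in both (129) and 658 went opposite ways, against 530 (163), 672 (215) and 128 with set A. COR47 (−2.6), COR15A (−1.36), COR15B (−0.97), LTI30 (−3.20) and ATG8B (−1.66) had a lower effect in inflorescence than in leaf, and LHCB4.3 (2.00) and JAL23 (2.45) a higher one. With set A as the inflorescence control, a setting added after seeing the data, ATG8B (0.29) and JAL23 (−0.93, adjusted p = 0.11) had the opposite sign and did not pass. COR47 (−1.69), COR15A (−2.56), COR15B (−2.04), LTI30 (−2.67) and LHCB4.3 (0.43) passed with the same sign. CCS (−0.70, adjusted p = 0.039) and AT1G12775 (−0.82, adjusted p = 0.014) also differed, while PHV (−0.19, adjusted p = 0.58), YAB5 (−0.26, adjusted p = 0.38) and PDF1.2 (−0.69, adjusted p = 0.3) did not pass. With set A, AT1G12775 (−1.05) and PHV (−0.74, adjusted p = 0.017) passed and CCS (−0.32, adjusted p = 0.41) did not.

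The share of called genes was compared between up to 500 measured genes on each side of the mutated gene and all other genes, and none of these tests passed. With 0 called genes in dcl4-2 leaf and 1 in rdr6-15 leaf, the tests of these comparisons could not pass. No conclusion is drawn from them. For dcl1-7 the window holds 501 genes, with 1 measured gene before DCL1 at the chromosome end and 500 after it. The odds ratio was 1.12 in dcl1-7 leaf (adjusted p = 0.688, Fisher's exact test), 1.27 in dcl1-7 inflorescence (adjusted p = 0.148), 0.844 in dcl4-2 inflorescence (adjusted p = 0.752) and 0.878 in rdr6-15 inflorescence (adjusted p = 0.688). QQS, the 1 named gene called in rdr6-15 leaf, lies within that distance of RDR6 (adjusted p = 0.227) but not within 250 genes. In dcl1-7 inflorescence a distance of 1000 genes gave 1.26 (adjusted p = 0.016). Lists that passed in no comparison of a mutant with its labelled control were those for heat shock proteins (smallest adjusted p = 0.158), anthocyanin synthesis (0.148), meiosis (0.134), floral meristems (0.27), cell wall loosening (0.264), trichomes (0.342) and roots (0.301). Against set A 3 further lists passed in dcl1-7 inflorescence. Of 10 meiosis genes 3 fell. The median was −0.18 (adjusted p = 0.0232, and adjusted p = 0.523 with an estimated correlation). Of 66 plastid transcripts 39 fell. The median was −1.05 (adjusted p = 5.92e-09, and adjusted p = 0.594 with an estimated correlation), where against set B it was −0.08 (adjusted p = 0.584). Of 10 tapetum genes of the wider list 6 fell. The median was −0.41 (adjusted p = 0.029, and adjusted p = 0.506 with an estimated correlation), and against set B it was 0.09 (adjusted p = 0.841).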

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

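The fits without 3 deviating arrays, the interaction with set A as control, the dcl1-7 lists against set A, the tests of RNA integrity for the Col-0 sets and for the pollen transcripts, of a batch shared by set B and dcl1-7 and of a loss shared by dcl4-2 were chosen only after the result was seen.

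A test of the difference between tissues (interaction, limma) picked out 51 probe sets for dcl4-2, 9 with a higher and 42 with a lower effect in inflorescence than in leaf, and 1574 at an unadjusted p under 0.05. The genes with the largest such differences were AT2G20625 (1.23), AT1G75300 (1.05) and AT2G34700 (1.04), and on the lower side AT3G05730 (−3.56), AT3G15450 (−2.78) and AT2G20670 (−1.99). The count was 17 without Col-0 set A replicate 1, 20 without dcl4-2 inflorescence replicate 2, 21 without set A replicate 3, 27 without Col-0 leaf replicate 1, 30 without dcl4-2 leaf replicate 1 or replicate 3, and 78 without dcl4-2 leaf replicate 2. Of 100 drawn splits of the labels within each tissue 3 gave as many calls, the real one included, and the highest other gave 94. The splits mix mutant and control arrays in both tissues, so they stand for no effect in either tissue. They cannot decide whether effects present in both tissues differ, and no conclusion on chance is drawn from them.

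The same test picked out 558 probe sets for rdr6-15, 205 higher and 353 lower. AT2G39400 (1.65), AT4G17470 (1.64) and AT4G26370 (1.26) led the higher ones, and the transcription factor UPB1 (−3.47), CYP71B31 (−3.24) and AT1G72290 (−2.79) the lower ones. The count was 351 without Col-0 set A replicate 3, 359 without rdr6-15 inflorescence replicate 2 and 363 without rdr6-15 inflorescence replicate 1. Of 100 drawn splits 2 gave as many, the real one included, with 575 in the highest other. For the same reason these splits do not decide whether the tissues differ.

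For dcl1-7 the test of the tissue difference picked out 5070 probe sets, 2877 higher and 2193 lower. The largest differences were those of AT2G33850 (4.56), AT5G62210 (4.48) and AT1G54020 (3.77), and of EXLA1 (−4.16), AT1G05340 (−3.60) and CML41 (−3.53). Of 100 drawn splits 1, the real one, gave as many, with 2997 in the highest other. A split with so many calls shows strong structure among these arrays. These splits too cannot decide whether effects present in both tissues differ. With set A as the inflorescence control the count was 3804, with AT5G62210 at −1.04 and AT1G05340 at 1.43, of opposite sign. AT1G54020 was then at 0.15 (adjusted p = 0.8) and no longer called, EXLA1 at −1.93, CML41 at −1.79 and AT2G33850 at 3.47. Leaf arrays had a 3' minus 5' difference of 2.59 to 4.16 and most inflorescence arrays of 0.72 to 1.17, so the tissues also differ in this measure. The leaf values begin at the level of the 3 deviating inflorescence arrays (2.36 to 2.59). What this does to the number of leaf calls was not tested.

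The Col-0 inflorescence sets differed in 10847 probe sets (10 splits of these 6 arrays are too few for a share under 0.05, with 1 as large, the real one, and 0 calls in the highest other). RNA integrity as the source is argued against by 12189 calls without the 3 deviating arrays, where the 3' minus 5' values of the sets overlap (0.95 and 0.84 in set B, 0.94 to 1.00 in set A). A different share of older flowers stays open: 10 flower-enriched pollen genes had a median of 0.12, but they ran from −1.41 (AtVEX1) to 0.90 (SETH2), so this median decides nothing. A cold or abscisic acid response of the set B plants stays open too, with 6 of 9 members of the wider list higher. Of the 3 genes of the first cold list, which are among these 9, limma called 2 lower and 1 higher (median −1.07). A batch shared by set B and dcl1-7 cannot be told apart from a mutant effect, since dcl1-7 showed a median share of 0.61 of the set difference (quartiles 0.45 and 0.73; −0.01 in dcl4-2 and −0.04 in rdr6-15) and an opposing effect of dcl1-7 may make up the rest; both sets are wild type, and no other difference between them was tested.

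The arrays of dcl4-2 inflorescence replicate 2, Col-0 set B replicate 3 and dcl1-7 inflorescence replicate 3 deviated together from their groups, with correlations of 0.72 to 0.78 across probe sets, 4967 probe sets higher and 4391 lower than on the other 6 arrays on all 3. Lower RNA integrity is a candidate explanation: their 3' minus 5' values lay 0.98, 1.13 and 0.93 above their group means (mean 1.02), against −0.62 to −0.37 on the other 6. A different share of older flowers is undecided at a mean difference of 0.16 in the pollen median. The plastid transcripts differed by a median of −0.48 on these arrays. These arrays share no group, so no effect of genotype was tested for them.

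In rdr6-15 inflorescence the pollen transcripts were lower. The 3' minus 5' value differed from set A by −0.18, without overlap, but RNA integrity as the whole cause is argued against by the slope of 10 flower-enriched pollen genes on that value within groups, over 15 inflorescence arrays, which predicts a median change of −0.03 (−0.08 to 0.12) where −0.76 was measured. A loss that dcl4-2 shares is argued against by a median of 0.17 for the same genes in dcl4-2. Fewer older flowers in the rdr6-15 harvest and an effect of rdr6-15 on pollen itself stay open and cannot be told apart: 90% of these genes were lower (quartiles −0.88 and −0.57), but they belong to the list that shows the pattern, so this supports neither.

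For the other comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 0 and 0 for dcl4-2 leaf, where all 10 splits gave 0, 4 and 0 for rdr6-15 leaf, 2142 and 5 for dcl1-7 leaf, 473 and 0 for dcl4-2 inflorescence, 1969 and 0 for rdr6-15 inflorescence, and 5314 and 4 for dcl1-7 inflorescence. They were 3 and 0 for dcl4-2 against rdr6-15 in leaf and 3513 and 0 in inflorescence, and in each comparison but dcl4-2 leaf 1 split, the real one, gave as many. The count of 0 in dcl4-2 leaf is that of limma, with 652 at an unadjusted p under 0.05.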

How the results depend on the processing

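The fits without the 3 deviating arrays, the interaction with set A as control, the dcl1-7 lists against set A and the calls in the same direction against both sets were chosen only after the result was seen.

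No result of a named gene reversed when the deposited values were quantile normalized again (206 results kept direction and side of the threshold, 1 stronger) or centred (147, with 1 weaker and 1 stronger). RMA had already equalized these values, so both settings change little and are a weak test of the processing. With a replicate left out 1380 kept both, 170 were weaker and 3 stronger, and only the QQS tissue difference in dcl1-7 turned (−0.31 to 0.01, the latter without set B replicate 3); it was 0.14 without the 3 deviating arrays. Counts with a replicate left out ranged from 0 to 3 for dcl4-2 leaf, 1 to 3 for rdr6-15 leaf, 1043 to 3842 for dcl1-7 leaf, 1.6e+02 (70 higher and 87 lower) to 390 for dcl4-2, 1035 to 1396 for rdr6-15 and 3910 to 5552 for dcl1-7 inflorescence, 0 to 3 and 2320 to 3030 for dcl4-2 against rdr6-15 in leaf and inflorescence, 9750 to 10546 for the Col-0 sets, 17 to 78, 351 to 618 and 4130 to 6666 for the tissue differences of dcl4-2, rdr6-15 and dcl1-7, and 40 to 47 for the gene lists (44 as reported). With an estimated correlation 0 lists passed (camera), against 44 of 180 at the preset correlation.

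Fits of only the 2 groups compared gave 2 calls in rdr6-15 leaf, 970 in dcl1-7 leaf, 219 in dcl4-2, 4476 in rdr6-15 and 3303 in dcl1-7 inflorescence, and 0 for dcl4-2 against rdr6-15 in leaf. Fits of all 27 arrays gave 19 in dcl4-2, 16 in rdr6-15 and 4055 in dcl1-7 leaf, 237 in dcl4-2 and 1253 in rdr6-15 inflorescence, and 41 for dcl4-2 against rdr6-15 in leaf. Array weights gave 3 in dcl4-2, 7 in rdr6-15 and 3547 in dcl1-7 leaf, and 1432 in dcl4-2 and 5254 in rdr6-15 inflorescence. With only probe sets of a single gene, which are fewer, there were 1 in rdr6-15 and 1072 in dcl1-7 leaf, 238 in dcl4-2, 936 in rdr6-15 and 2662 in dcl1-7 inflorescence, and 1 and 1761 for dcl4-2 against rdr6-15. At a 2-fold minimum there were 371 in dcl1-7 leaf, 44, 285 and 654 in the dcl4-2, rdr6-15 and dcl1-7 inflorescence, and 480 for dcl4-2 against rdr6-15. At an adjusted p of 0.01 there were 1 in rdr6-15 and 790 in dcl1-7 leaf, 141, 818 and 3283 in the dcl4-2, rdr6-15 and dcl1-7 inflorescence, and 0 and 1788 for dcl4-2 against rdr6-15 in leaf and inflorescence. Without the 3 deviating arrays dcl4-2 inflorescence had 916. A window of 1000 genes gave an odds ratio of 1.26 for dcl1-7 inflorescence, and rdr6-15 against set B a correlation of 0.043 with dcl4-2. Quantile normalization moved the share of higher calls for dcl4-2 against rdr6-15 in leaf from 33.3% to 50%, as 1 higher and 2 lower calls became 1 higher and 1 lower. Beyond stricter thresholds and fewer probe sets, the cause was not tested.

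The choice of Col-0 inflorescence set moved the inflorescence counts too. With the other set, calls were 11427 in dcl4-2, 11894 in rdr6-15 and 8010 in dcl1-7, and with both sets 210 in dcl4-2 and 232 in dcl1-7; 542 were called in the same direction against each set in dcl1-7. With the other set, these log2 changes had the opposite sign. In dcl4-2 they were AT3G62550 −0.50, EXO −1.33 and COR47 −0.23, and in rdr6-15 AT1G22890 −3.64, AT5G61590 −0.73, AT2G39400 −1.38, CYP71B31 0.08, AT1G72290 0.31, SWEET7 1.72, PAM68 −0.35, CHLM −0.17 and THI2.1 2.05. In dcl1-7 they were CYP71B31 −0.58, AT5G62210 −2.63, AT5G52390 −0.95, GILT −1.38, AT1G21520 0.35, CHI 0.25, AT5G52760 0.29, AT1G09500 1.62, AT3G60420 0.51, AT1G05340 2.09, THI2.1 −0.38, JMT −0.53, UGT76B1 0.37, CML37 0.05, APS3 −0.20, ATG8H 1.28, ATG8E 1.56, APG8A 1.03, AUR1 −0.83, PRL −2.10, AUR2 −1.11, WES1 2.28, CHIL −1.12, SBPASE −0.14, AGO7 −0.15, SPT 0.77 and SAG101 0.45. With both sets the sign turned for EXO (−0.08) in dcl4-2, for AT1G22890 (−0.90), AT2G39400 (−0.02), SWEET7 (0.63) and THI2.1 (0.53) in rdr6-15, and in dcl1-7 for ATG8E (0.41), APG8A (0.17), AUR1 (−0.07), PRL (−0.51), AUR2 (−0.23), WES1 (0.75), CHIL (−0.10) and SPT (0.18). Of the dcl1-7 tissue differences printed, those of AT5G62210 (−1.04), AT1G05340 (1.43), ARPN (−0.38), APS3 (−0.67), ATG8B (0.29) and JAL23 (−0.93) turned with set A. Of the dcl1-7 lists that passed against set B, the medians turned against set A for cell division (−1.11), defence (0.05), flavonoid (−0.29) and autophagy genes (0.96). For auxin-responsive genes the test turned and the median kept its sign (−0.04). The median of the wider tapetum list, which passed only against set A, turned as well (−0.41). The sets differ in 10847 probe sets; why they differ was not settled, and the cause was not tested further.

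No paired analysis was possible because the labels give no replicate numbers, and those used here follow only the order of deposit. Same-numbered arrays correlated above 0.1 in their deviations for 13 of 18 pairs in leaf (−0.152 to 0.545) and 10 of 30 in inflorescence (−0.672 to 0.722). In leaf their first component (35.1% of the variance) was above 0 on all 4 arrays numbered 1 and below 0 on all 4 numbered 3, a hint from the data and not the design. No fit blocked by these numbers was run. This component therefore stays in the spread behind the leaf calls, and its effect on their number was not tested. Signal over background limits weakly expressed genes, whose differences RMA compresses, and 3 arrays per group limit the calls of small changes.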

Other observations

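Every test in this part was planned, and the genes in it were chosen after their values were seen. A few genes moved through several of the mutants. Mutants set against the same Col-0 arrays share the error of that control, so their changes are not independent. QQS had log2 changes of 0.53, 2.16 and −1.37 in the leaf and 1.44, 3.06 and −1.54 in the inflorescence of dcl4-2, rdr6-15 and dcl1-7, with 5 of the 6 called (adjusted p = 1 in dcl4-2 leaf). It is the only named gene called in rdr6-15 leaf, and the Col-0 inflorescence sets differed in it by only 0.08. AT1G63150 rose by 0.56, 0.77 and 0.79 in the inflorescence of the same mutants, each against its labelled control. Set B (4.89 ± 0.08) lay below set A (5.30 ± 0.01), and against set A the rise of AT1G63150 in dcl1-7 was 0.39. Its RFL relative AT1G12775 differed by 1.00, 0.95 and 1.22 in leaf, and was called in dcl1-7 alone. These differences were all taken from the same Col-0 leaf arrays, so a low control value would raise each of them.

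CCS, a miR398 target, rose by 1.18 in dcl1-7 leaf and fell by 0.63 in dcl4-2 inflorescence. CHLI2 of chlorophyll synthesis fell by 0.69 in dcl1-7 leaf and rose by 0.58 in rdr6-15 inflorescence. The dehydrin LTI30 rose by 2.64 in dcl1-7 leaf and by 1.47 in rdr6-15 inflorescence. WRKY53 fell in the inflorescence of each mutant, by 1.33 in dcl4-2 and by 0.92 in rdr6-15, which share set A as control, and by 1.64 in dcl1-7 against set B.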
